A study of Mus musculus with 9 samples.

How the data were processed

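Livers of 9 wild-type mice were sequenced, 3 in each of the groups CHOW, MCD and MCDDRUG, which were taken from the sample titles and diet labels. RNA was total RNA, and the sequencing itself is not described in the labels beyond the makers of the kits. The deposited table holds 17806 genes with a symbol and an NCBI gene identifier, 17753 of which matched the reference gene table. For each library it holds an estimated count as deposited, of the fractional form that RSEM gives, and an FPKM and a TPM value, named as such per the file headers. HISAT2 2.0.4, Bowtie2 2.2.5 and RSEM 1.2.12 are named per the submitters' processing notes, which do not say what each did. The genome build and annotation are not given in the sources used here, so no positions are printed. The 9 mean columns that the authors deposited were not used. Of the expected counts as deposited, 47.1% were whole within 0.005, and they were rounded to whole numbers, which moved no library total by more than 0.000417%. Reads from overlapping genes, antisense genes and near-identical copies such as the Mup, Cyp2, Cyp3a and Serpina1 families are divided by RSEM's model and are uncertain for single genes.

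The design had assumed FPKM values and limma on log2(FPKM + 1), and named edgeR as the test if counts were found. Since the table holds counts, edgeR's quasi-likelihood test was the main test and limma on log2(FPKM + 1) became an alternative. Scalings, trend, robust fitting, array weights and block, first meant for FPKM values, were then run on the counts. Genes with a mean FPKM of at least 0.5 over the 9 libraries (11670) were tested in 1 model with all 3 groups, TMM normalization and Benjamini-Hochberg adjustment at 0.05, with edgeR 4.0.16, limma 3.58.1 and R 4.3.3. The biological coefficient of variation was 30.3%. Errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM values are TMM-normalized and given as mean ± SD. Ratios against a group with 0 counts use a floor of 3 counts over the group. A gene with 0 to 3 counts in a group has an exact binomial 95% interval of the ratio, which covers counting error only.

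The design also held 40 lists of genes and cell type markers (839 genes, 740 of them tested). Lists with at least 5 tested genes (38) entered limma's camera with a preset correlation of 0.01 on log2 CPM with a prior count of 2, and pancreatic acinar and adipose markers were too few to enter. Camera with an estimated correlation and fry were alternatives, adjusted over the 38 lists. Counts of list members are given over all genes tested and adjusted over the list alone. The latter are not adjusted for the 38 lists tried in each comparison. Of 11670 genes tested, 3174 had an unadjusted p under 0.05 in edgeR's test of MCD against CHOW. There were 2960 for MCDDRUG against MCD and 2057 for MCDDRUG against CHOW. Counts over a list alone were not tested against this background, so a share of members near it does not set a list apart. Lists overlap in part, and C6 is on both the Kupffer cell and the male-biased list.

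Genes are named by a rule fixed beforehand. It takes the 6 largest rises and the 6 largest falls among genes past the threshold with a mean FPKM of at least 1 and no overlap between groups, leaving out unnamed gene models, then 30 anchor genes, and then up to 4 members of each described list with the smallest p and any that went against their list. Genes that mark single libraries (Acta1, Ckm, Alb, Hbb-bs, Ctrb1) were chosen after their values were seen.

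The test was tried on simulated data, negative binomial counts drawn from the real means, library sizes and dispersions of 11670 genes, with 200 genes changed in each of 5 runs per comparison. It recovered 19.8% of 2-fold and 81.8% of 4-fold changes for MCD against CHOW, 24% and 85% for MCDDRUG against MCD, and 20.2% and 81.2% for MCDDRUG against CHOW, with 4.69%, 5.87% and 4.34% false calls. Camera, tried for MCDDRUG against MCD only, called a list of 25 genes raised 2-fold in 5 of 5 runs. It also called 1 of 185 lists without a change. Simulated genes varied independently and these lists were drawn at random, so this check cannot show how often camera calls lists of correlated genes falsely.

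Alternatives were limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 5 and with quantile normalization, no filter, a filter at a mean FPKM of 5, upper-quartile and DESeq2 (1.42.0) size factors, library sizes without the 20 highest genes, no dispersion trend, robust fitting, limma-voom with array weights, DESeq2 itself, a fit of only the groups compared, the replicate number as a block, and leaving out each library. Added after the data were seen were a fit without CHOW replicate 2 and MCDDRUG replicate 3, and a correction of each library for transcript length and GC content, with and without the block. Length came from the ratio of deposited counts to FPKM and GC from GENCODE M21 transcripts matched by symbol, for 95.8% of tested genes. Shared libraries were weighed with 20 simulated data sets without any change. Replicates of a group differed far beyond counting error (a chi-square of 34.5 to 434 per gene), so none was a repeat sequencing of the same library. This cannot tell a further preparation of the same liver from another liver.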

Results

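RNA-seq was used to measure gene expression in 9 livers of wild-type mice, 3 in each of the groups CHOW, MCD and MCDDRUG. The series is about QZTGT, the herbal formula Qing-Zhi-Tiao-Gan-Tang, in non-alcoholic steatohepatitis, and each sample came from a different liver. MCD is the usual short name of a diet without methionine and choline that brings on steatohepatitis in mice, although the labels do not spell it out. MCDDRUG is read here as MCD with QZTGT, since the design text names no other treatment. All 9 titles give week 5, while another label of MCDDRUG replicate 5 gives week 6. Libraries held between 18414098 (MCD replicate 1) and 20601243 (CHOW replicate 1) counts, so that 3 counts corresponded to 0.141 to 0.176 CPM, the usual scale of counts relative to library size. Of 17806 genes in the table, 11670 passed the expression filter and were tested.

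A pair of libraries stood apart from the others of their groups. MCDDRUG replicate 3 held skeletal muscle transcripts, with Acta1 (skeletal muscle actin) at 3763 TPM (transcript abundance relative to the library total) and Ckm (muscle creatine kinase) at 1600 TPM, against at most 0.46 and 0.25 TPM in the other libraries. Its median correlation with the other libraries across genes was 0.867, against 0.936 to 0.948 for the rest. CHOW replicate 2 held an acute phase pattern. Saa1 (serum amyloid A1) stood at 56014 TPM there, against 498 and 193 TPM in CHOW replicates 1 and 5, and Alb (albumin) took 2.6% of its counts against 8.04% and 12% in the same replicates. Libraries also differed in short transcripts, within groups as well. The 973 tested genes under 1 kb had median log2 deviations from the mean of the 9 libraries of 0.47, 0.155 and -0.238 in CHOW replicates 1, 2 and 5, of -0.213, -0.287 and -0.356 in MCD replicates 1, 2 and 7, and of 0.291, -0.118 and 0.245 in MCDDRUG replicates 2, 3 and 5. CHOW replicate 5 thus lay among the MCD libraries. The group means differed by -0.41 between MCD and CHOW and by 0.43 between MCDDRUG and MCD, and those of the 2798 genes over 4 kb by 0.26 and -0.30.

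**Figure D1:**
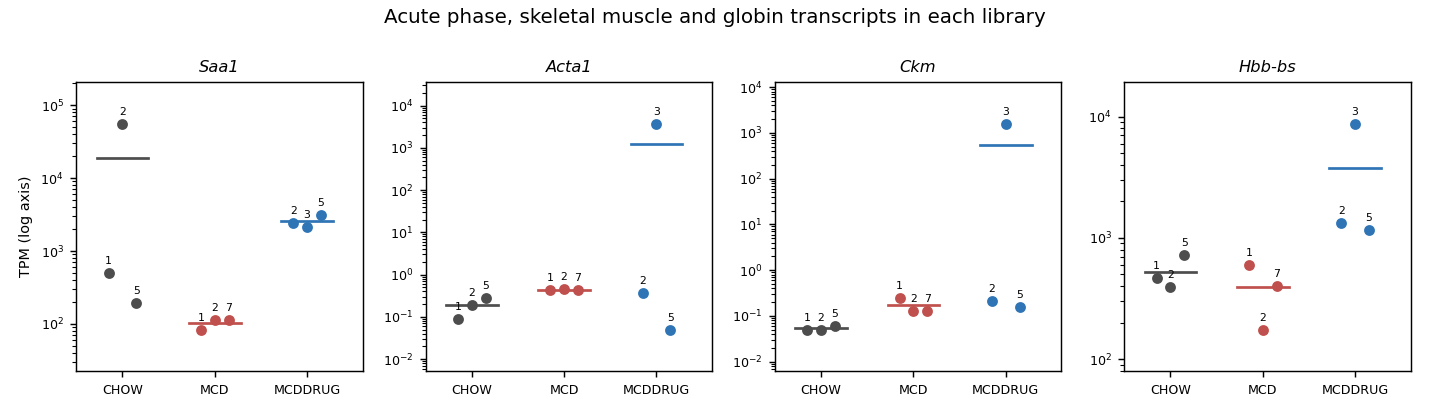
Saa1, Acta1, Ckm and Hbb-bs (a beta globin) in TPM on log axes, with 1 numbered point per liver library in the groups CHOW, MCD and MCDDRUG and a horizontal line at each group mean. Saa1 reached 56014 TPM in CHOW replicate 2, and Acta1 reached 3763 TPM in MCDDRUG replicate 3.

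The MCD and CHOW livers were compared to find which genes differed with the MCD condition. Genes whose liver expression depends on sex through growth hormone were among those with the largest changes. Of 23 male-biased genes tested, 12 fell over all genes tested and 19 fell when adjusted over the list alone, with a median log2 fold change of -2.77 (adjusted p = 0.416 with an estimated correlation). Socs2, a feedback inhibitor of growth hormone signaling, went the other way, at 1.14 ± 0.35 (a rise when adjusted over the list alone). Of 12 female-biased genes, 7 rose, and 9 rose when adjusted over the list alone, with a median of 2.61 (adjusted p = 0.0385 with an estimated correlation), while Cyp17a1 was at -1.78 ± 0.69, a fall when adjusted over the list alone. Among the male-biased genes, C6 (complement component 6, NCBI gene 12274) fell by 2.51 ± 0.20 (SE) on the log2 scale, and Cyp4a12b (a fatty acid hydroxylase, NCBI gene 13118) fell by 6.64 ± 0.57. Hsd3b5, a steroid-metabolizing enzyme, went from 24.6 ± 19.2 CPM (SD, n = 3) in CHOW to 0.34 ± 0.14 CPM in MCD.

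Large falls were also seen in secreted proteins of male mouse urine and plasma, of which Mup7 and Mup17 are on the male-biased list as well. That list holds several Mup genes and both Cyp4a12 genes. Its counts and median thus rest in part on close copies that share reads and are not independent. Serpina1e, a serine protease inhibitor, fell by 7.60 ± 0.86 on the log2 scale, from 6909 ± 4036 to 35.6 ± 19.4 CPM. It is 1 of 5 Serpina1 copies, which together summed to 42203 ± 5184 CPM in CHOW, 25144 ± 1999 CPM in MCD and 24113 ± 2473 CPM in MCDDRUG, a log2 ratio of -0.75 in MCD against CHOW, so the size of its fall is uncertain. Mup15 fell by 13.5 ± 2.25 on the log2 scale and Mup7 by 8.23 ± 1.76. Mup17 had 215 counts in CHOW and 0 in MCD, 82.1-fold lower with a floor of 3 counts over the group. Its ratio of MCD to CHOW had a 95% counting interval of 0 to 0.0151, and it passed in 2 of 9 fits that left out 1 library. The Mup genes encode major urinary proteins and are near-identical copies among which reads are easily misassigned, so single members are uncertain, and without 1 library Mup15 lay between -17.5 and -10.75 and Mup7 between -9.53 and -6.39. Their 22 members together summed to 31153 ± 16338 CPM (SD, n = 3) in CHOW and 1496 ± 1312 CPM in MCD, with no overlap. The largest rises were in Cyp2a4 (8.32 ± 1.01), Cyp3a44 (7.25 ± 1.07), Cyp2b13 (7.23 ± 0.85), Sult1e1 (6.91 ± 0.61), the estrogen sulfotransferase, and Fmo3 (6.60 ± 0.72), a flavin monooxygenase. These Cyp2, Cyp3a and Sult genes also have close copies. Sult2a3 rose as well, from 1 count in the 3 CHOW libraries together to 190 in MCD, a ratio of 165.9 with a 95% counting interval of 29.4 to 6587.

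**Figure D2:**
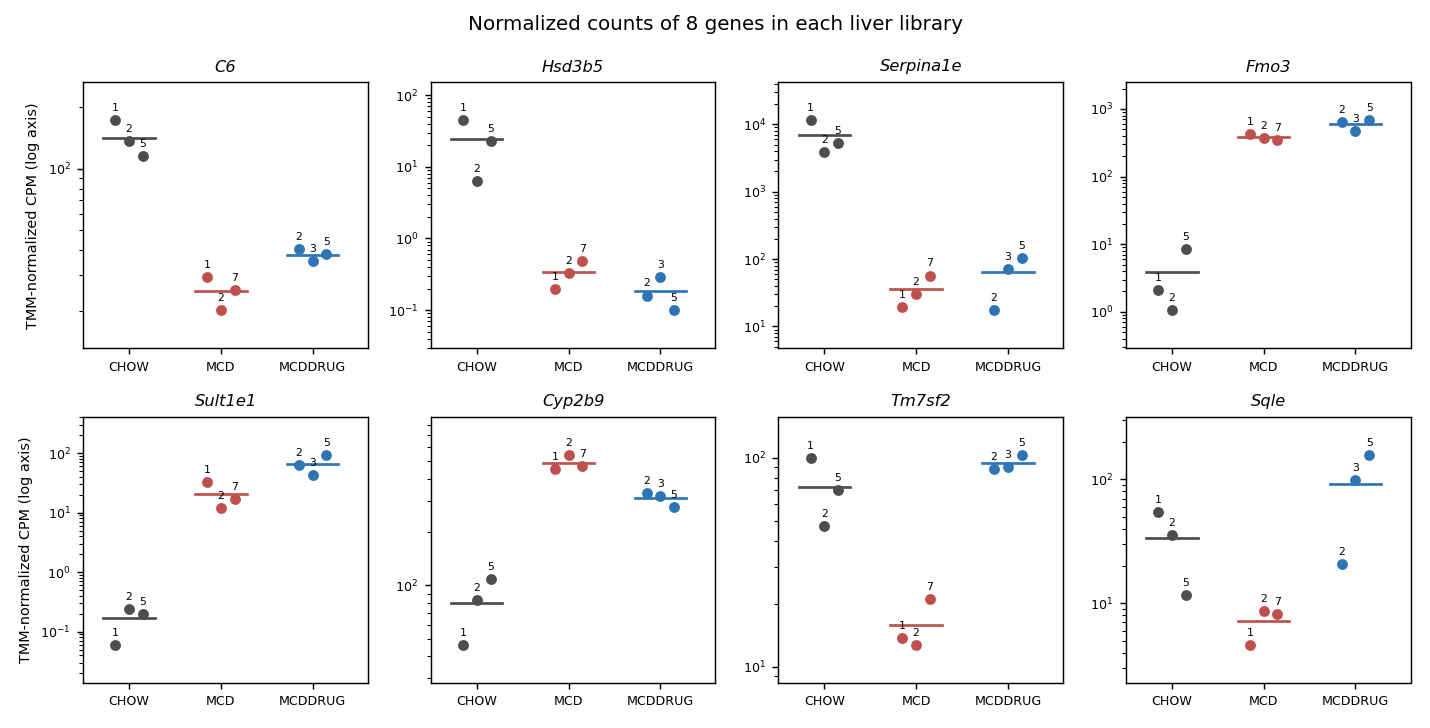
Normalized CPM on log axes for 8 genes, with 1 numbered point per liver library and a horizontal line at each group mean. C6, Hsd3b5 and Serpina1e were lower and Fmo3, Sult1e1 and Cyp2b9 higher in all MCD and MCDDRUG libraries than in all CHOW libraries, and Tm7sf2 and Sqle were higher in all MCDDRUG than in all MCD libraries.

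Some NRF2 and xenobiotic metabolism genes rose in MCD, while neither list call held with an estimated correlation (adjusted p = 0.681 for both). Of 29 NRF2 and glutathione genes, 4 rose (9 when adjusted over the list alone), among them Gstm3 (3.24 ± 0.38), the transporter Abcc4 (1.93 ± 0.26), Osgin1 (2.31 ± 0.45) and Nqo1 (0.89 ± 0.18). Gstp1 went the other way, at -1.66 ± 0.37 with adjusted p = 0.0528 over all genes and 0.00733 over the list. Of 29 xenobiotic metabolism genes, 4 rose (Fmo3, Cyp2b9, Cyp2b13 and Cyp3a44), 11 when adjusted over the list alone, and all 4 are also on the female-biased list. Cyp2c54 (-1.88 ± 0.42) and Ces2a (-1.43 ± 0.45) went against that list, lower when adjusted over the list alone. Of 27 collagen and matrix genes, 3 rose, namely Pdgfra (1.51 ± 0.27), Tagln (2.40 ± 0.47) and Acta2 (1.73 ± 0.36), the smooth muscle actin of activated stellate cells, and 13 rose when adjusted over the list alone, while Col1a1 was at 0.32 ± 0.15 with adjusted p = 0.209 (list adjusted p = 0.681 with an estimated correlation). Pdgfra, Tagln and Acta2 passed in 4, 4 and 2 of 9 fits that left out 1 library. Among 22 macrophage markers, Gpnmb (4.71 ± 0.74), Mmp12 (4.28 ± 0.79) and Cd63 (1.61 ± 0.31) rose, and Fabp5 was at -1.40 ± 0.35, a fall when adjusted over the list alone (list adjusted p = 0.682 with an estimated correlation). Among cell cycle genes, 2 of 20 rose (6 when adjusted over the list alone), with Ccnd1, the cyclin D1 gene, at 3.32 ± 0.52 and Mcm6 at 1.37 ± 0.25 (list adjusted p = 0.682 with an estimated correlation).

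Among cholesterol synthesis genes, Tm7sf2, a sterol reductase, fell by 2.19 ± 0.29 on the log2 scale and was the only 1 of 25 to fall over all genes tested (3 when adjusted over the list alone), and the list median was -0.90 (adjusted p = 0.682 with an estimated correlation). Fatty acid oxidation genes had a median of -0.39, with no call among 31 over all genes tested and 9 falls and 1 rise (Cyp4a31) when adjusted over the list alone, with Creb3l3 at -1.19 ± 0.28 and Acaa1a at -1.22 ± 0.29. This list, like the cholangiocyte and stellate lists, had adjusted p = 0.682 with an estimated correlation. Its counts adjusted over the list alone stand beside 3174 of 11670 genes at an unadjusted p under 0.05 in edgeR's test. They were not tested against that background. Cholangiocyte markers had a median of 2.0, with no call over all genes tested and 6 of 9 when adjusted over the list alone, and their median was 0.68 with quantile normalization. Krt19, the bile duct keratin, stood at 35.1, 4.89 and 1.55 CPM in MCD replicates 1, 2 and 7, against 0.76 to 0.85 CPM in CHOW. Stellate cell markers had a median of 0.56 (no call over all genes, 5 of 14 when adjusted over the list alone). B and plasma cell markers were lower when adjusted over the list alone in 4 of 6 cases and in none over all genes, with Jchain, the joining chain of antibodies, at -1.79 ± 0.44 (list adjusted p = 0.681 with an estimated correlation). The 48 cytosolic ribosomal protein genes had a median of -0.38 with no call by either adjustment, in a comparison in which short transcripts as a whole were at -0.41, and their camera call ended with a length and GC correction (median 0.03, adjusted p = 0.441) and with quantile normalization (0.066, adjusted p = 0.263). Their adjusted p was 0.682 with an estimated correlation.

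In all, 239 genes differed between MCD and CHOW at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test, 113 higher and 126 lower. The split was 11 higher and 27 lower without CHOW replicate 2. It was 14 and 8 without MCD replicate 1 and 21 and 8 without MCD replicate 2, and nearer to even without any other single library. With library sizes taken without the 20 highest genes the split was 712 higher and 82 lower, and with limma on log2(FPKM + 1) it was 365 and 93, while the median of all genes was 0.34 and 0.20 with these scalings and -0.013 with TMM. The groups did not overlap for 31.8% of genes, where chance gives 10%. The competitive list test camera called 18 of 38 lists, 9 higher and 9 lower, and 11 of the 18 stayed called in all 9 fits that left out 1 library. The macrophage, T and NK cell, endothelial, hepatocyte identity, periportal, interferon and ribosomal calls each ended in at least 1. Of these calls only that of the female-biased list held with an estimated correlation. With quantile normalization the calls of fatty acid oxidation (median -0.057, adjusted p = 0.454), cell cycle (0.13, 0.200), hepatocyte identity (0.26, 0.0957) and periportal genes (0.047, 0.841) ended too, as did those of cell cycle (0.0628) and endothelial genes (0.0740) with library sizes without the 20 highest genes. With the length and GC correction those of interferon (0.0694) and T and NK cell genes (0.124) ended, and without CHOW replicate 2 and MCDDRUG replicate 3 those of endothelial (0.0966) and periportal genes (0.0947). The rotation test fry, which asks whether a list moves on balance, called the male-biased (adjusted p = 0.00506) and female-biased (0.000158) lists. The gene count was 18, 38 and 1404 without CHOW replicates 1, 2 and 5, 22, 29 and 374 without MCD replicates 1, 2 and 7, 125, 456 and 95 without MCDDRUG replicates 2, 3 and 5, and 96 without CHOW replicate 2 and MCDDRUG replicate 3. C6, Cyp4a12b, Serpina1e, Sult1e1, Fmo3, Cyp2b9 and Cyp2a22 passed in all 9 fits that left out 1 library, while the other 27 of 34 named calls were lost in at least 1. Among these, Mup7, Mup17, Acta2 and Osgin1 passed in only 2 of the 9 fits. Nqo1, Cd63, Mcm6 and Chac1 passed in 3, and Pdgfra, Tagln and Mmp12 in 4.

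**Figure D3:**
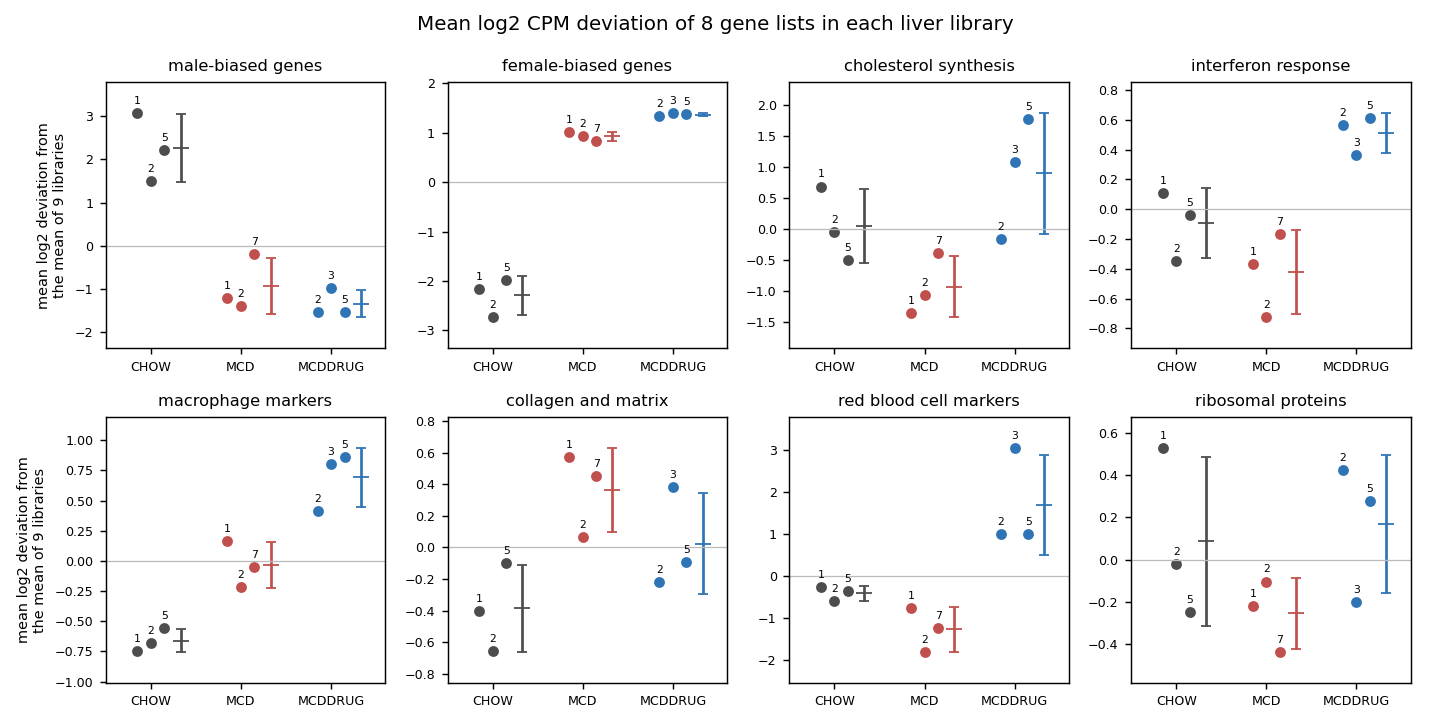
Mean log2 CPM deviation from the mean of the 9 libraries for 8 gene lists, with 1 numbered point per liver library and the group mean with its SD beside the points. All MCD and MCDDRUG libraries lay below all CHOW libraries for male-biased genes and above them for female-biased genes, and all MCDDRUG libraries lay above all MCD libraries for interferon response, macrophage, cholesterol synthesis and red blood cell genes.

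The MCDDRUG and MCD livers were compared to find which genes differed with the added treatment. Cholesterol synthesis genes had the smallest p among the lists (camera adjusted p = 2.22e-11). No gene on that list or any other passed over all genes tested, but 23 of 25 cholesterol synthesis genes were higher when adjusted over the list alone, with a median log2 fold change of 1.86 (adjusted p = 0.499 with an estimated correlation). Tm7sf2 was at 2.57 ± 0.30 (SE), Sqle (squalene epoxidase) at 3.69 ± 0.76, Mvd at 3.65 ± 0.79 and Hmgcr, the rate-limiting enzyme of the pathway, at 3.03 ± 0.70. Hmgcr went from 16.6 ± 2.40 CPM (SD, n = 3) in MCD to 136 ± 103 CPM in MCDDRUG, with 30.5, 141 and 236 CPM in replicates 2, 3 and 5. Fatty acid synthesis genes had a median of 0.41 with no call among 21 by either adjustment, with Fasn (fatty acid synthase) at 1.67 ± 0.79 (list adjusted p = 0.712 with an estimated correlation).

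Interferon response genes had a median of 1.07, and 14 of 23 were higher when adjusted over the list alone, among them Zbp1 (1.98 ± 0.33) and Isg15 (1.26 ± 0.20), with a list adjusted p = 0.474 with an estimated correlation. Antigen presentation genes had a median of 0.66 (6 of 12 when adjusted over the list alone, Tap1 at 0.95 ± 0.21), monocyte-derived macrophage markers 0.71 (8 of 22, Fabp5 at 2.35 ± 0.36) and Kupffer cell markers 0.71 (5 of 10, Cd5l at 0.84 ± 0.22). These lists had adjusted p = 0.499, 0.474 and 0.527 with an estimated correlation. B and plasma cell markers had a median of 1.06 (4 of 6, Jchain at 1.63 ± 0.43) and T and NK cell markers 0.68 (2 of 8, Gzma at 1.92 ± 0.52), both with adjusted p = 0.499 with an estimated correlation. Red blood cell markers had a median of 3.50, with 6 of 7 higher when adjusted over the list alone, among them Gypa (4.85 ± 0.77), Slc4a1 (3.85 ± 0.55) and Hbb-bs (3.37 ± 0.74), with a list adjusted p = 0.499 with an estimated correlation. Neutrophil markers had a median of 1.75 with no call by either adjustment, Elane at 3.81 ± 1.02 and Mpo at 3.72 ± 1.13 (list adjusted p = 0.641 with an estimated correlation). The neutrophil median lay between 0.40 and 2.66 over the alternatives, with an adjusted p of up to 0.211, and the mean log2 deviation of these markers was 0.61, -0.40 and -2.60 in MCD replicates 1, 2 and 7. The 8 globin genes summed to 2131, 8727 and 1525 CPM in MCDDRUG replicates 2, 3 and 5 and to 179 to 602 CPM in MCD, so that the library with muscle transcripts also held the most globin. Cell cycle genes had a median of 0.51 with no call by either adjustment, Mki67 at 1.56 ± 0.45 (list adjusted p = 0.499 with an estimated correlation).

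Cholangiocyte markers had a median of -1.21, with 5 of 9 lower when adjusted over the list alone (Krt19 at -3.94 ± 1.03), and bile acid genes a median of -0.26, with 3 of 26, the bile salt export pump Abcb11 at -1.73 ± 0.36, Abcg8 at -0.92 ± 0.19 and Hsd3b7 at -0.68 ± 0.15. These lists had adjusted p = 0.601 and 0.527 with an estimated correlation. Collagen and matrix genes had a median of -0.26, with Tagln (-2.06 ± 0.46) lower and Tgfb1 (0.76 ± 0.20) higher when adjusted over the list alone, and Acta2 at -0.95 ± 0.35 (list adjusted p = 0.712 with an estimated correlation). Sex-biased genes did not pass in this comparison, at medians of -0.41 for the male-biased and 0.37 for the female-biased list (camera adjusted p = 0.335 and 0.467). Ribosomal protein genes had a median of 0.43 with no call by either adjustment, beside 0.43 for all genes under 1 kb, and their median with the length and GC correction was 0.02 (adjusted p = 0.992). Their adjusted p was 0.712 with an estimated correlation.

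Over all genes, 0 passed in edgeR's quasi-likelihood test (2960 at an unadjusted p under 0.05, smallest adjusted p = 0.0831, 565 at an adjusted p under 0.1). DESeq2 called 1124 genes, limma-voom with array weights 1389, limma with quantile normalization 121 and limma on log2(FPKM + 1) 0. The groups did not overlap for 33% of genes, where chance gives 10%. Camera called 18 of 38 lists, 15 higher and 3 lower, and none of these calls held with an estimated correlation. In all 9 fits that left out 1 library 12 of the 18 stayed called, while the collagen, cholangiocyte, acute phase, fatty acid synthesis, bile acid and lysosomal calls each ended in at least 1. Fry called the interferon response (adjusted p = 0.0244), monocyte-derived macrophage (0.0244) and red blood cell (0.0315) lists. The edgeR count was 3 without CHOW replicate 2, 4 without MCD replicate 7, and 4 without CHOW replicate 2 and MCDDRUG replicate 3, where the cholesterol synthesis, interferon and red blood cell medians were 1.81, 1.14 and 2.32. The camera call ended for bile acid genes (adjusted p = 0.119) and fatty acid synthesis genes (0.0653) without those libraries. It also ended for collagen (0.146), chemokine (0.0546) and lysosomal genes (0.0735) with the length and GC correction, for lysosomal (0.418), fatty acid synthesis (0.0903) and acute phase genes (0.0538) with quantile normalization, and for lysosomal (0.106) and bile acid genes (0.0546) with library sizes without the 20 highest genes. NRF2 genes, at 0.0769 without these changes, were called lower with the correction (0.00181) and with quantile normalization (0.00421).

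The MCDDRUG and CHOW livers were compared to find how far treated livers were from those on chow. Sex-biased genes were again among those with the largest changes. Of 23 male-biased genes, 7 fell (18 when adjusted over the list alone, median -3.83, adjusted p = 0.115 with an estimated correlation), Socs2 being at 0.89 ± 0.35, and 8 of 12 female-biased genes rose (9 when adjusted over the list alone, median 2.27, adjusted p = 0.00688 with an estimated correlation). Sult1e1 rose by 8.61 ± 0.62 on the log2 scale, from 0.16 ± 0.09 CPM (SD, n = 3) to 66.9 ± 25 CPM, followed by Cyp2a4 (8.51 ± 1.02), Cyp3a44 (7.51 ± 1.07), Fmo3 (7.26 ± 0.74), Cyp2b13 (5.97 ± 0.84) and Cyp3a41a (5.21 ± 0.88). Cyp4a12a fell by 8.78 ± 0.92 and Cyp4a12b by 8.47 ± 0.67, with 11 and 5 counts left in MCDDRUG, so that without 1 library the values reached -11.3 and -12.3 and their size is uncertain. Hsd3b5 fell by 7.0 ± 0.81, and falls were also seen in Serpina1e (-6.75 ± 0.83), Mup21 (-4.50 ± 0.56) and Mup20 (-4.05 ± 0.55). The 22 Mup genes summed to 2073 ± 1081 CPM in MCDDRUG.

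Some macrophage markers also rose in MCDDRUG over CHOW. Of 22 monocyte-derived and lipid-associated markers, Cd63 (2.49 ± 0.32), Lgals3 (1.58 ± 0.22) and Gpnmb (4.49 ± 0.73) rose, and 20 rose when adjusted over the list alone (adjusted p = 0.0420 with an estimated correlation). Cell cycle genes had a median of 1.30 with no call over all genes tested and 15 of 20 higher when adjusted over the list alone, Ccna2 at 2.10 ± 0.43 (list adjusted p = 0.144 with an estimated correlation). Slc4a1, the red cell anion exchanger, rose by 4.41 ± 0.58, 1 of 7 red blood cell markers to pass (6 when adjusted over the list alone), in a group whose replicate 3 held the most globin (list adjusted p = 0.479 with an estimated correlation). Gstm3 rose by 3.43 ± 0.39, 1 of 29 NRF2 genes (6 higher when adjusted over the list alone), while Gstp1 (-1.93 ± 0.37) and Txnrd1 (-0.46 ± 0.15) were lower when adjusted over the list alone (list adjusted p = 0.533 with an estimated correlation). The lysosomal genes Atp6v0d2, a proton pump subunit, and Cd63 rose, 2 of 30, and 5 when adjusted over the list alone (list adjusted p = 0.496 with an estimated correlation). Fatty acid oxidation genes had a median of -0.43 with no call over all genes tested and 4 of 31 lower when adjusted over the list alone, Cyp4a10 at -2.03 ± 0.42 (list adjusted p = 0.496 with an estimated correlation). Cholesterol synthesis genes had a median of 0.99 with no call among 25 by either adjustment (adjusted p = 0.594 with an estimated correlation). Des, the desmin gene of stellate and muscle cells, was at 4.95 ± 1.56 in the group with the muscle transcripts.

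There were 46 genes past the threshold in edgeR's test, 28 higher and 18 lower. Without CHOW replicates 1, 2 and 5 in turn, 13, 10 and 5 were higher and 18, 18 and 9 lower. Higher genes stayed more numerous in each fit without an MCD or MCDDRUG library. The split was 36 higher and 14 lower with library sizes taken without the 20 highest genes, where the median of all genes was 0.18 (-0.024 with TMM), and 28 and 28 with limma and quantile normalization. The groups did not overlap for 20% of genes, against 10% by chance. Camera called 20 of 38 lists, 15 higher and 5 lower, and 10 of the 20 stayed called in all 9 fits that left out 1 library. The stellate, Kupffer, hepatocyte identity, periportal, antigen presentation, fatty acid synthesis, cholesterol synthesis, one-carbon, NRF2 and lysosomal calls each ended in at least 1. The female-biased and macrophage calls held with an estimated correlation. Sult1e1, Fmo3, Cyp4a12a, Cyp4a12b, Serpina1e and C6 passed in all 9 fits that left out 1 library, while the other 15 of 21 named calls were lost in at least 1. Among these, Cyp3a41a passed in only 1 of the 9 fits, Gpnmb in 3 and Cyp3a44 in 4. The gene count was 28 and 14 without CHOW replicates 2 and 5, 28 without MCD replicate 2, 25 and 15 without MCDDRUG replicates 2 and 5, and 36 without CHOW replicate 2 and MCDDRUG replicate 3. Without that pair of libraries the camera calls of collagen (adjusted p = 0.218), stellate (0.873), Kupffer (0.0891), hepatocyte identity (0.193), periportal (0.332) and fatty acid synthesis (0.156) genes ended, and acute phase genes became a call (median 0.94, adjusted p = 6.02e-13). The calls of hepatocyte identity (0.741) and one-carbon genes (0.106) ended with quantile normalization, and those of stellate (0.0532), Kupffer (0.0519) and fatty acid synthesis genes (0.0652) with library sizes without the 20 highest genes.

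The title of the series speaks of a corrected expression pattern, so fold changes of both steps were set against each other. Of the 239 genes called between MCD and CHOW, 0 also passed between MCDDRUG and MCD, where no gene passed at all, so no overlap was possible. With other settings, each among its own calls, genes called in opposite directions came to 434 with DESeq2 and 610 with limma-voom and array weights. They came to 1 with edgeR's robust setting and 31 with quantile normalization. Across the 11670 genes, which are not independent replicates, Pearson's r was -0.31 and Spearman's rho -0.59, and r was -0.54 without MCDDRUG replicate 3. Fold changes had the same sign for 25.2% of genes, against 33.3% in simulated unchanged groups. Both contrasts hold the MCD libraries. The simulations gave a mean r of -0.50 and a covariance of -0.0958, against an observed covariance of -0.251, a difference of -0.155. Of 1401 genes at an unadjusted p under 0.05 in both tests, 1372 had opposite signs. In the simulations 127 of 128 on average had them, so shared libraries alone bring this share near its ceiling and it cannot tell a reversal. The number of such genes can differ, and 1372 lay above the highest of the simulations without any change, 146. Simulated genes varied independently and no group was changed. Correlated genes, or a change in CHOW or MCDDRUG alone, can therefore exceed that range, and the count cannot tell a reversal either. Independent lists would give 403, a value that leaves out the shared MCD libraries. No split of 3 MCD libraries leaves 2 on each side, so part of any excess may come from the shared libraries. Of the 46 genes called between MCDDRUG and CHOW, 35 were also called in the same direction between MCD and CHOW, against 0.465 for independent lists, a value that leaves out the shared CHOW libraries. The simulations called too few genes to give a count for these. The covariance of these fold changes was 0.333, against 0.0970 in simulations, a difference of 0.236.

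The values of further genes chosen before the data were examined follow, whether or not they passed. Cd36, a fatty acid carrier, was at 1.93 ± 0.42 (SE) in MCD against CHOW with adjusted p = 0.0515, and Hmox1, a heme oxygenase, at 1.15 ± 0.27 with adjusted p = 0.0577. Mat1a, which makes the methyl donor of the liver, was at -1.37 ± 0.38 (adjusted p = 0.0776) and Bhmt, which remethylates homocysteine, at -1.21 ± 0.73. Pemt, the enzyme that makes phosphatidylcholine, was at -0.08 ± 0.27 in MCD against CHOW. Il1b was at -2.20 ± 0.68 and Trem2, a receptor of lipid-associated macrophages, at 0.97 ± 0.41. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 0.01 ± 0.58, Ppara at 0.18 ± 0.38, Plin2 at -0.59 ± 0.69, Scd1 at -0.68 ± 1.37, Fgf21 at 1.36 ± 1.35 and Srebf1 at 0.70 ± 0.28. Cpt1a was at -0.57 ± 0.19, Pparg at 0.26 ± 0.22, Mttp at -0.35 ± 0.22, Fasn at -0.29 ± 0.77, Hmgcr at -0.88 ± 0.66 and Sqle at -2.24 ± 0.73. Abcb11 was at 1.09 ± 0.35, Nr0b2 at -1.35 ± 0.45, Spp1 at 0.60 ± 0.31, Ccl2 at -0.58 ± 0.62, Tgfb1 at -0.10 ± 0.20 and Adgre1 at 0.23 ± 0.26. Between MCDDRUG and MCD, Tgfb1 was at 0.76 ± 0.20 (adjusted p = 0.0955), Trem2 at 0.74 ± 0.40, Adgre1 at 0.56 ± 0.26 and Col1a1 at -0.02 ± 0.15. None of the chosen genes passed there or in MCDDRUG against CHOW. Those not yet given for MCDDRUG against MCD lay between -2.39 ± 1.41 (Fgf21) and 1.86 ± 1.40 (Scd1). Timp1 and Tnf lay below the expression filter, at mean FPKM values of 0.361 and 0.226.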

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

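The fits without CHOW replicate 2 and MCDDRUG replicate 3, and those with the length and GC correction, were chosen after seeing the data, and all other alternatives before. For MCD against CHOW (239 genes), limma on log2(FPKM + 1) called 458 genes, pseudocounts of 0.1 and 5 gave 514 and 492, the stricter filter (fewer genes tested) 159, library sizes without the 20 highest genes 794, array weights 1728, DESeq2 1561, the replicate block 465, the fit without CHOW replicate 2 and MCDDRUG replicate 3 96, and leaving out 1 library 18 to 1404. For MCDDRUG against MCD (0 genes), the values were 2 with a pseudocount of 0.1, 121 with quantile normalization, 1 with robust fitting, 1389 with array weights, 1124 with DESeq2, 1 with the block, 3 with only the groups compared, 4 without CHOW replicate 2 and MCDDRUG replicate 3, 1 with block and correction, and 0 to 4 without 1 library. For MCDDRUG against CHOW (46 genes) they were 91 with limma, 130 with a pseudocount of 0.1, 648 with DESeq2, 70 with the length and GC correction, 24 with block and correction, and 14 to 61 without 1 library. Genes called in opposite directions (0) came to 1 with a pseudocount of 0.1, 31 with quantile normalization, 1 with robust fitting, 610 with array weights, 434 with DESeq2, 1 with the block, 1 with only the groups compared, 2 without CHOW replicate 2 and MCDDRUG replicate 3, 1 with block and correction, and 0 to 4 without 1 library. The correlation between those fold changes (-0.31) was -0.51 with limma, -0.48 and -0.50 with pseudocounts of 0.1 and 5, -0.49 with quantile normalization, -0.41 with no filter, -0.52 with array weights, -0.65 with the block, -0.50 without CHOW replicate 2 and MCDDRUG replicate 3, -0.61 with block and correction, and -0.54 to -0.27 without 1 library. Of the lists called (18, 18 and 20 in the order above), 1, 0 and 2 were called with an estimated correlation and 2, 3 and 4 with fry, 10 with the stricter filter in the first comparison, and 11 with block and correction in the second. List medians that turned sign in MCD against CHOW included hepatocyte identity (0.26) and periportal genes (0.047) with quantile normalization, ribosomal proteins (0.066 with quantile normalization, 0.028 with the correction, 0.059 with block and correction) and oxidative phosphorylation (0.35, 0.28 and 0.25). With library sizes without the 20 highest genes, where all genes had a median of 0.34, those of hepatocyte identity (0.033), ribosomal proteins (0.00025) and oxidative phosphorylation (0.30) were also above 0, and the calls of the former pair stayed lower relative to other genes. The acute phase median was 0.14 with quantile normalization and 0.20 without CHOW replicate 2 and MCDDRUG replicate 3, where the stellate median in MCDDRUG against CHOW was -0.091. In MCDDRUG against MCD oxidative phosphorylation turned to -0.22 with quantile normalization, -0.22 with the correction and -0.29 with block and correction. At adjusted p = 0.584 and 0.335 without these changes, it was called in the turned directions with quantile normalization (adjusted p = 6.95e-07 in MCD against CHOW, 0.00374 in MCDDRUG against MCD), with the correction (0.000154 and 2.92e-05) and with block and correction, while the block alone called it higher in MCDDRUG against MCD (0.35, adjusted p = 0.00905). For Saa2, MCDDRUG against CHOW, the log2 fold change of -4.02 turned to 3.76 without CHOW replicate 2 and MCDDRUG replicate 3, and lay between -4.60 and 3.59 without 1 library, the latter without CHOW replicate 2. The causes of these differences were not tested. For single genes, 4085, 4391 and 4377 of the values in the order above kept their side of the threshold. Newly passing were 329, 204 and 111, and 177, 0 and 102 no longer passed. For lists these were 700, 709 and 722, then 53, 33 and 39, then 33, 49 and 33. Changes of direction were set apart only where the main fit or the alternative passed (0, 0 and 1 for genes, 8, 3 and 0 for lists). Values that kept their side may thus have changed sign. Replicate numbers were not seen to pair the libraries. Deviations of libraries with the same number correlated at -0.14 to 0.24 across genes, and those of other libraries from different groups at -0.20 to 0.22. So few pairs cannot exclude a pairing. Scalings and array weights chosen for FPKM values were run on the counts instead, and TMM factors computed on FPKM values were not run. Depth limits genes near 3 counts, such as Sult2a3 and Mup17, whose folds rest on a floor or have wide intervals.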

Other observations

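Of the tests weighed here, that of a treatment response for muscle transcripts, that of Y-linked genes and all 3 on opposite changes were chosen after the result was seen. Genes of methionine, choline and one-carbon metabolism had a median log2 fold change of -0.28 in MCDDRUG against CHOW, with no call among 35 over all genes tested and 1 higher and 6 lower when adjusted over the list alone (adjusted p = 0.496 with an estimated correlation). Cbs, which starts the conversion of homocysteine to cysteine, was at -0.94 ± 0.24 (SE), Chpt1 at -0.63 ± 0.17, and Mthfd1l, a mitochondrial folate enzyme, went the other way at 1.43 ± 0.29. The call ended without CHOW replicate 2 and MCDDRUG replicate 3 (adjusted p = 0.332). In MCD against CHOW, Chac1, which degrades glutathione and is a target of the amino acid starvation response, rose by 2.55 ± 0.48, and Psat1 of serine synthesis was at 2.61 ± 0.95. Periportal genes had a median of -0.48 there, with no call over all genes and 4 of 13 lower and 1 higher (Cdh1) when adjusted over the list alone (adjusted p = 0.682 with an estimated correlation), Pck1 at -0.84 ± 0.19 and Asl of the urea cycle at -1.81 ± 0.46. The list medians of periportal and hepatocyte identity genes turned sign with quantile normalization, and that of hepatocyte identity was 0.033 with library sizes without the 20 highest genes.

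Saa1 was at 2448, 2137 and 3114 TPM in MCDDRUG replicates 2, 3 and 5, at 83.4, 113 and 115 TPM in MCD, and at 498 and 193 TPM in CHOW replicates 1 and 5. Acute phase genes had a median of 0.56 in MCDDRUG against MCD with no call among 20 by either adjustment (camera adjusted p = 0.0135, adjusted p = 0.712 with an estimated correlation), and Hamp, the iron hormone hepcidin, was at -1.39 ± 0.53. Ctrb1, a pancreatic enzyme, stood at 17.2 TPM in MCD replicate 1 and at most 0.41 TPM elsewhere.

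Skeletal muscle transcripts in MCDDRUG replicate 3 were weighed first. A separate list of 10 muscle genes had a median log2 ratio of 4.88 in that library over the highest of the other 8, as muscle tissue taken with the liver piece would give, and 20 muscle genes took 2.14% of its TPM. Against a response of liver cells to the treatment, the median of those 20 genes in MCDDRUG replicates 2 and 5 over MCD was -0.051. Muscle taken at dissection is therefore a candidate source, as a hypothesis, and a mix of samples at a later step stays open.

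Male-biased genes were lower and female-biased genes higher in MCD than in CHOW. Female animals in MCD and MCDDRUG are argued against by Y-linked genes, whose lowest sum in those 6 libraries was 83.1% of the CHOW mean. Reads moved between Mup copies are argued against by their summed counts, at a log2 ratio of -4.38. With the length and GC correction the male-biased median was -2.56 and the female-biased median 2.75. That correction was at most 0.822 on the log2 scale in any library. It could not have removed a male-biased median of -2.77, so this test could have no other outcome. The fitted trend is thus too small to be the whole cause of the male-biased falls. A response to the diet or to growth hormone may lie behind it, a hypothesis that these libraries do not test further. Of the 10 splits of the 6 libraries, 1 (the real one) reached 239 genes and the highest other gave 2; for MCDDRUG against CHOW 1 reached 46 and the highest other gave 0, and 10 splits are too few for a share under 0.05.

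Fold changes in MCD against CHOW and in MCDDRUG against MCD had a negative covariance across genes, at -0.201 when group means of log2 CPM are compared. The variance between the shared MCD libraries gives a term of -0.0532 alone. These libraries as the whole cause are argued against by the remaining -0.148, negative in each of the 9 fits without 1 library though its size varied (-0.0826 without MCD replicate 2, -0.225 without MCD replicate 7), and the muscle and acute phase libraries by the 114% of it kept without them. A length and GC trend stays open as part of it, since 68% was kept with that correction, and 44.7% to 82.1% when 1 library was left out. A partial return with the treatment is a hypothesis and may hold only in part, as such a trend cannot be told apart from it here. By camera with the preset correlation, lists did not all return. Macrophage markers were called higher at both steps, and the male-biased median was -2.77 in MCD and -3.83 in MCDDRUG, each against CHOW. Cholesterol synthesis and interferon genes were called lower in MCD than in CHOW and higher in MCDDRUG than in CHOW. Others, such as collagen and cholangiocyte genes, were called higher in MCD and then lower in MCDDRUG. None of these calls held with an estimated correlation. For MCDDRUG against MCD all 10 splits gave as many genes as the real one, 0 (2960 at an unadjusted p under 0.05 in edgeR, 1124 called by DESeq2 and 1389 by limma-voom with array weights), the highest other gave 0, and 10 splits are too few for a share under 0.05. With a real count of 0 no split could give fewer, so that all 10 reached it was fixed in advance and tells nothing.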
